A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

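Polyadenylated RNA of 2 wild-type and 2 ulp1-I615N libraries was measured by RNA sequencing, with a directional library kit according to the labels' protocols. The deposited table holds raw fragment counts per gene, made by the authors with featureCounts; per the file headers this was version 2.0.0, run on read pairs with neither the strand option, the multi-mapping option nor the option for overlapping features. Strand was therefore ignored in the counting, fragments that map to several places were not counted, and fragments over more than 1 gene were not counted, so overlapping genes, antisense genes and near-identical copies are uncertain. The submitters' processing notes name HISAT2 2.1.0, Subread 2.0.0 and the build sacCer3. The version of the gene annotation is not given in the sources used here. Groups and replicate numbers were taken from the sample titles, and the columns were tied to samples by the library names in the sample descriptions.

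The table lists 7126 features. Of these, 6048 matched a RefSeq gene of the R64 assembly by locus tag, 6036 of them with the same start and end, and gene symbols were taken from that match; 1078 features kept the identifier of the table. No feature lay beyond the reference length of its nuclear chromosome. In all, 374 features had 0 counts in each library, among them the 55 mitochondrial features, whose 0 counts cannot be read as expression. The list of mitochondrially encoded proteins therefore had 0 tested genes, and the list of the 2-micron plasmid had 0 because its 5 names are not among the features of the table. Total counts ran from 13244131 to 26723470, a ratio of 2.02, and a count of 0 allows up to 0.227 CPM (counts scaled to a common library size) in the shallowest and 0.112 in the deepest library (3 counts of the total, for counting error only). The 50 most abundant genes held 21.0% to 22.5% of the counts.

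Replicates were compared before use. The chi-square per degree of freedom of counts over genes was 9.86 between the wild-type libraries and 9.06 between the mutant libraries, far above sampling noise, so they were kept as separate libraries, and between groups it was 112 to 167.

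The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (robust dispersion estimates, TMM normalisation, and the default filter on low counts, with a minimum count of 10 and a minimum total count of 15), mutant against wild type without a replicate block, with Benjamini-Hochberg adjustment and a threshold of 0.05. It covered 6139 genes, of which 860 overlap another feature, and the common biological coefficient of variation was 0.0572. Standard errors of log2 fold changes were derived from the F statistics. Gene lists, chromosomes and genes within 20 kb of a chromosome end were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, two-sided, and adjusted within each family. Of 44 lists fixed before the data were examined, 41 had at least 4 tested genes and were tested; the strain markers were not, and 8 names in the lists were not found. The interval of a chromosome's median came from 2000 bootstrap draws over genes, and windows of 20 neighbouring genes used genes with a mean of 50 counts or more.

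Genes are named by a rule fixed before the data were examined: the mutated gene and the strain markers; the 10 largest rises and the 10 largest falls among called genes with a mean of 50 counts or more per library whose mutant libraries both lie on the same side of both wild-type libraries; and up to 4 called members of each list that was called or had at least 3 called members, by size of change, or the 2 members with the smallest p in other lists. The alternatives fixed in advance were other scalings, other filters, DESeq2 1.42.0, limma-voom, the older quasi-likelihood method, a test against a fold of 1.2, thinning to the smallest total, totals without the 50 most abundant genes, the replicate block, each library left out, an estimated correlation, fry, a background without ribosomal genes, and subtelomeric distances of 10 and 30 kb. Leaving out chromosome X or removing its median was added after seeing the data. With 1 library left out, the lone library of its group is assumed to vary like the other group.

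The test was tested on simulated data drawn from the means, dispersions and library sizes of these libraries for the comparison of the mutant with wild type over 6139 genes, with 50 genes changed at each fold. The changed genes were drawn from those with a mean of 50 counts or more, so recovery at lower counts was not measured. They were far fewer than the genes called in the data, so recovery there may differ. At an adjusted p under 0.05 the edgeR test recovered 68% of the genes changed 1.25-fold, 94% of those changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold, with 15 calls among unchanged genes. In a second simulation 3 shifted gene sets were each called, and 0 of 55 other sets were. The simulated genes varied independently and no gene outside the 3 sets was shifted. This simulation therefore does not test how correlation between genes affects the list calls.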

Results

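Polyadenylated RNA of budding yeast (Saccharomyces cerevisiae) was sequenced from a wild-type strain and from a strain that carries the ulp1-I615N allele of ULP1, the gene of the protease that matures the small protein modifier SUMO and takes it off its target proteins. Both strains were of mating type a, carried the same set of auxotrophic markers in the labels, and were harvested in mid-log growth in rich glucose medium. Each group held 2 libraries. The totals of counted fragments were 15448419 and 19346393 in wild type replicates 1 and 2, and 13244131 and 26723470 in the mutant replicates 1 and 2. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The comparison asks which transcripts differ between the strain with the mutant protease and its wild type.

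The transcript of the mutated gene itself was not called different. ULP1 (YPL020C, chromosome XVI, 512313 to 514178 of sacCer3) was counted 1118 and 1213 times in the wild-type libraries and 1116 and 2061 times in the mutant libraries. This came to 70.6 ± 5.39 and 77.1 ± 3.72 CPM (counts scaled to a common library size, SD, n = 2 each; log2 fold change 0.12 ± 0.08 SE, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.197). With library totals only the value was 0.26 and passed (adjusted p = 0.0248). With 1 library left out it was not called, at 0.08 without mutant replicate 1, 0.19 without wild type replicate 1 and 0.05 without wild type replicate 2. A point mutation need not alter the amount of its transcript, so this value does not check the labels. The marker LYS1, disrupted in both genotypes, had 4 and 5 counts in the wild-type libraries and 4 and 5 in the mutant libraries. ADE2 and ADE3, which both genotypes list as deleted, were nevertheless counted in each library. ADE2 had 6190 and 6621 counts in wild type and 3116 and 7104 in the mutant, and ADE3 had 2327 and 2388 in wild type and 1368 and 3250 in the mutant. After scaling, ADE2 was 1.62-fold lower and ADE3 1.32-fold lower in the mutant (edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.69e-05 and adjusted p = 0.00632). URA3 was 1.31-fold lower (adjusted p = 0.000476), and LEU2 (log2 fold change 0.16, adjusted p = 0.0513) and TRP1 (0.11, adjusted p = 0.475) were not called. TRP1 was 0.24 without mutant replicate 1, -0.07 without mutant replicate 2 and 0.07 without wild type replicate 1. LEU2 passed under several alternatives, among them library totals only (0.29, adjusted p = 0.00111).

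The mutant differed from wild type in a large part of the transcriptome. Genes of chromosome X were higher almost along its full length, by a median of 1.66-fold. Elsewhere in the genome, genes of the general stress response, chaperones, respiration and the proteasome were higher, and genes of ribosomes, ribosome assembly, translation and purine synthesis were lower. These directions are those of lists called with a preset correlation between genes, and with an estimated correlation 0 of 41 lists were called. Of 6139 genes tested, 1618 were higher and 1489 lower in the mutant at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 3032 were not called. Most of these changes were small: 2104 of the 3107 changed genes (67.7%) differed by under 1.5-fold, and 361 differed at least 2-fold, 318 of them higher and 43 lower. The values of the groups did not overlap for 74.1% of the tested genes, against 33.3% given by chance. With library totals as the only scaling, the median of all genes moved up by 0.13 on the log2 scale and the split became 2192 higher and 855 lower, so directions of small changes are relative to that shift.

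Chromosome X stood apart from the other nuclear chromosomes. Of its 373 tested genes, 336 were higher (90.1%), 2 were lower and 35 were not called, whereas 22.2% of the genes elsewhere were higher. The median log2 fold change was 0.73 (95% bootstrap interval over genes 0.69 to 0.78), with 0.72 in mutant replicate 1 and 0.73 in mutant replicate 2, while the wild-type libraries differed by a median of 0.0045. Chromosome X held 5.58% of the counts in each wild-type library, and 9.13% and 9.16% in the mutant libraries. The other 15 nuclear chromosomes had medians from -0.06 to 0.04. The rise ran from end to end: in 334 windows of 20 neighbouring genes the median lay between 0.48 and 0.99, against -0.37 to 0.34 in windows of the other chromosomes. Chromosome X alone was called by limma's camera over chromosomes (adjusted p = 1.08e-45, and adjusted p = 0.0169 with an estimated correlation). Known genes on it include KAR2, the chaperone of the endoplasmic reticulum, at 1.08 ± 0.08 (SE), and SOD1, the copper and zinc superoxide dismutase, at 1.33 ± 0.09, the sterol enzyme gene ERG20 at 0.84 ± 0.07 and the nucleoporin gene NSP1 at 0.62 ± 0.06. The genes that were lower were VTC4 of polyphosphate synthesis, at -0.28, and MET3 of sulfate assimilation, at -0.23, named after their values were seen. Both mutant libraries had the raised chromosome X, so the comparison of the strains holds the ULP1 allele and chromosome X together. Away from chromosome X, 1282 of 5766 tested genes were higher and 1487 lower, with 224 and 43 of them at least 2-fold.

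**Figure D1:**
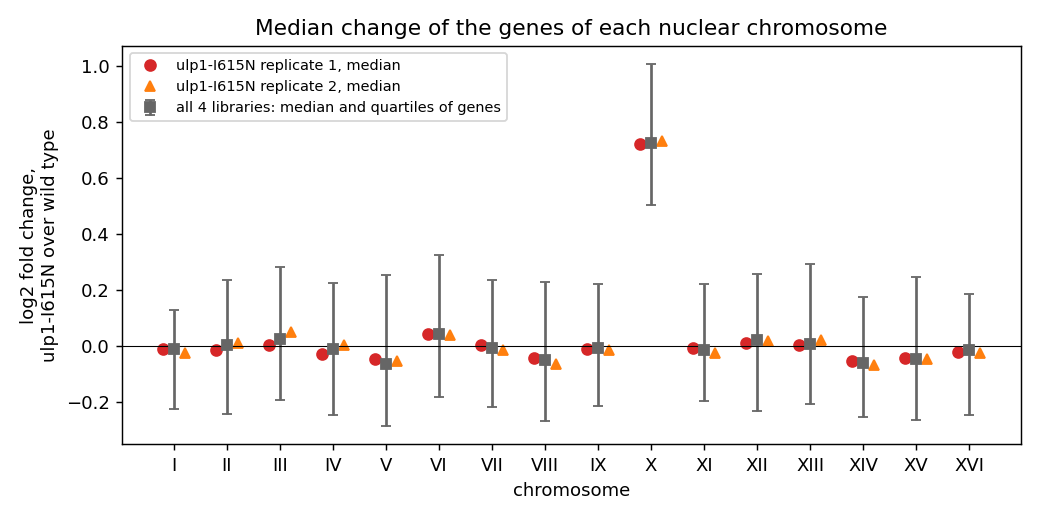
Median log2 fold change (ulp1-I615N over wild type) of the tested genes of each nuclear chromosome; grey squares and bars are the median and quartiles over genes from all 4 libraries, and coloured points are the medians of each mutant library against the mean of the wild-type libraries. Chromosome X lies at 0.73, and the other 15 chromosomes lie between -0.06 and 0.04.

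**Figure D2:**
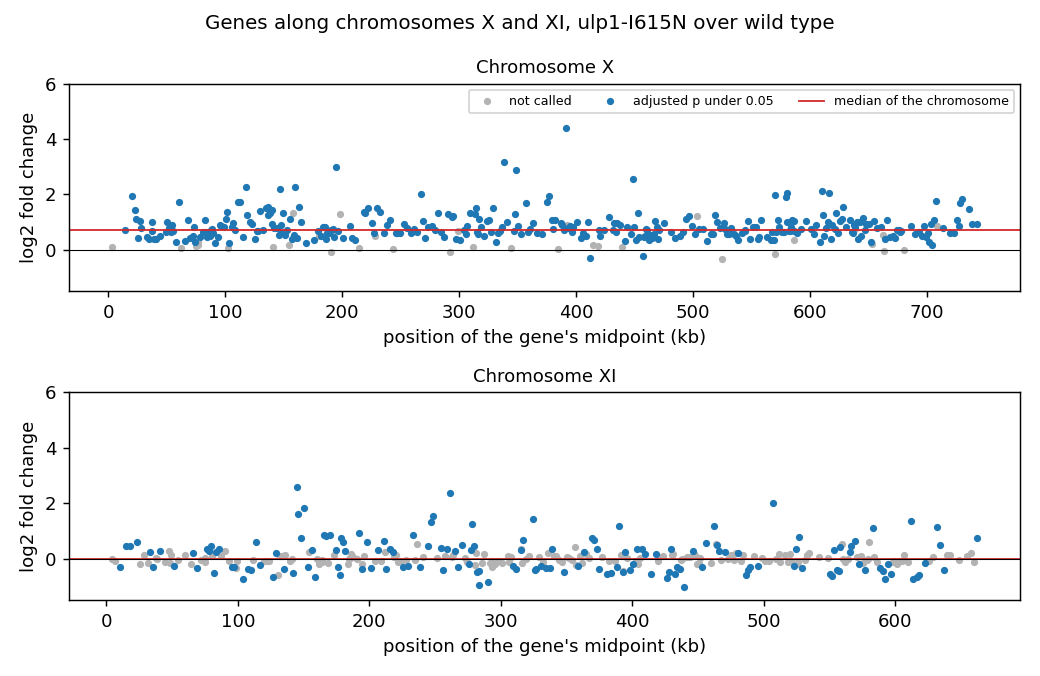
Log2 fold change (ulp1-I615N over wild type) of each tested gene by position in kb on chromosome X and, for comparison, on chromosome XI; blue points have an adjusted p under 0.05, grey points are not called, and the red line is the median of the chromosome. On chromosome X 336 of 373 genes were higher along the full length, and on chromosome XI 78 of 331 were.

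The largest rises were led by genes of the general stress list. HSP12 (YFL014W, chromosome VI, 107256 to 107585), which encodes a small membrane-associated stress protein, rose 37.3-fold, from 6.19 ± 0.37 to 232 ± 8.14 CPM (SD, n = 2 each; log2 fold change 5.22 ± 0.09 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.49e-14). DDR2 (YOL052C-A, chromosome XV, 231570 to 231755), a gene induced by many stresses, rose 18.3-fold. TMA10 (YLR327C, chromosome XII, 783127 to 783387) rose 16.6-fold, and HSP26 (YBR072W, chromosome II, 382030 to 382674), the gene of a small heat shock protein, rose 15.8-fold. The next largest rises were those of SUE1 at 9.46-fold, the hydrophilin gene GRE1 at 9.20-fold, the glyceraldehyde-3-phosphate dehydrogenase gene TDH1 at 9.03-fold, NCA3 from 24.2 to 193 CPM, the hydrophilin gene SIP18 at 7.65-fold and the small heat shock protein gene HSP42 at 7.17-fold. TDH1 and NCA3 lie on chromosome X. SUE1 overlaps another annotated feature, and TDH1 has close paralogs, so the counts of both are uncertain.

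The largest falls included those of a pair of neighbouring genes on chromosome IV and of genes of phosphate and metal uptake. BSC1 (YDL037C, 384601 to 385587) fell from 62.9 ± 8.66 to 4.04 ± 0.67 CPM (SD, n = 2 each; log2 fold change -3.91 ± 0.14 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.86e-10). PRM7 (YDL039C, 381985 to 384081), a gene named for its regulation by pheromone, fell 11.3-fold (log2 fold change -3.49 ± 0.22, edgeR adjusted p = 0.000167, and 0.0838 without mutant replicate 1). PHO84 (YML123C, chromosome XIII, 24037 to 25800), the high-affinity phosphate transporter gene, fell 8.27-fold, from 714 ± 37.6 to 86.5 ± 4.41 CPM. SPL2, a regulator of low-affinity phosphate uptake, fell 4.03-fold, PHM6 2.90-fold, the high-affinity zinc transporter gene ZRT1 3.25-fold and the ferric reductase gene FRE4 2.89-fold. VTC3 (YPL019C, chromosome XVI, 514511 to 517018), a gene of polyphosphate synthesis that lies beside ULP1, fell 2.93-fold. YHR219W, which overlaps 2 other features near a chromosome end, and YER138W-A fell 9.13-fold and 2.98-fold, and their counts are uncertain because fragments shared between repeated sequences were not counted.

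**Figure D3:**
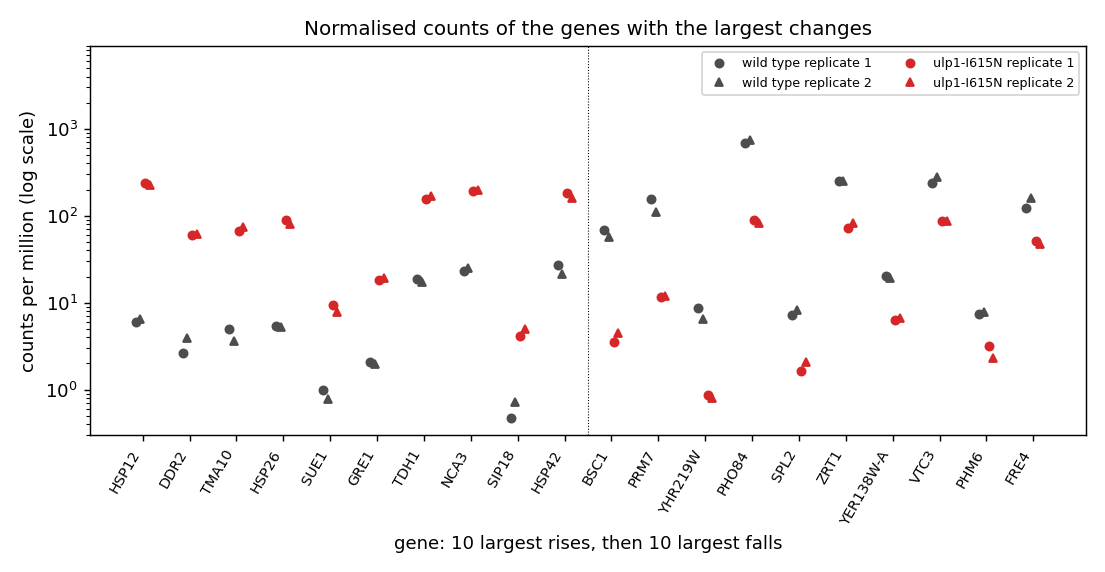
Normalised CPM (log scale) of the 10 genes with the largest rises and the 10 with the largest falls in each of the 4 libraries; grey marks are wild type and red marks are ulp1-I615N, with circles for replicate 1 and triangles for replicate 2. For each gene both mutant libraries lie on the same side of both wild-type libraries, as the rule for naming these genes required; HSP12 rises from 6.19 to 232 and PHO84 falls from 714 to 86.5.

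Of the 41 gene lists tested, 22 were called by camera with a preset correlation between genes, 11 of them higher and 11 lower. With an estimated correlation 0 of the 41 lists were called after Benjamini-Hochberg adjustment, so each camera call was made with the preset value only. With the estimated setting camera takes its degrees of freedom from the 4 libraries, which leaves little power over 41 lists. Its lack of calls therefore does not show that correlation between genes made the preset calls. With fry, which allows for that correlation but does not compare a set with other genes, 28 lists were called. The nuclear pore and ergosterol lists were not among them. The smallest unadjusted p with an estimated correlation was 0.0318, for the general stress response. Without the genes of chromosome X, which was tried after seeing the data, 21 of the 22 called lists remained called. Library totals as the only scaling reduced the counts of lists with small falls: nuclear pore genes went from 21 lower to 5, RNA polymerase III genes from 11 lower and a median of -0.22 to 5 lower and -0.09, methionine and sulfate genes from 18 lower and -0.22 to 10 lower and -0.09, and ergosterol genes from 15 lower and -0.20 to 8 lower and -0.07. M/G1 and daughter-cell genes went from 20 lower and -0.28 to 15 lower and -0.15, and translation factor genes from 33 lower and -0.36 to 26 lower and -0.23. Among rises, the median of the DNA damage list went from 0.19 to 0.32 and that of the retrograde list from 0.12 to 0.25.

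Stress genes rose broadly. Of 65 tested genes of the general stress response, targets of the activators Msn2 and Msn4, 60 were higher, 1 was lower and 4 were not called, with a median log2 fold change of 1.38 (61 higher and 1 lower when adjusted over the list alone, camera adjusted p = 3.68e-26, adjusted p = 0.310 with an estimated correlation). HSP12, DDR2, TMA10 and HSP26 led this list, and 3 of its members lie on chromosome X. Of 36 heat shock factor targets 31 were higher, 1 was lower and 4 were not called (median 0.58, 31 and 1 adjusted over the list alone, camera adjusted p = 1.26e-12, adjusted p = 0.310 with an estimated correlation). Among them the cytosolic chaperone gene SSA1 rose from 536.5 ± 17.5 to 2009 ± 89.2 CPM (SD, n = 2 each; log2 fold change 1.90), and HSP78, the gene of a mitochondrial chaperone, rose by 1.81 on the log2 scale. SSA1 overlaps another feature and has a close paralog in SSA2. HSP26, HSP42, HSP104, SSA4 and GRE3 are members of both the general stress and the heat shock factor lists, so these rises are not separate. Proteasome genes rose by a smaller and more uniform amount: 33 of 39 were higher, 0 lower and 6 not called (median 0.30, 34 and 0 adjusted over the list alone, camera adjusted p = 1.46e-07, adjusted p = 0.310 with an estimated correlation). The catalytic subunit gene PRE3, on chromosome X, was at 0.97, the proteasome adaptor gene ECM29 at 0.87 and the assembly factor gene UMP1 at 0.48.

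Cell wall and redox genes were also higher. In the cell wall integrity list 26 of 42 genes were higher, 6 lower and 10 not called (median 0.32, 28 and 6 adjusted over the list alone, camera adjusted p = 1.66e-05, adjusted p = 0.310 with an estimated correlation). The cell wall protein genes PIR3 and CWP1 rose by 2.59 and 2.35 on the log2 scale, SPI1 by 1.95 and the kinase-like gene KDX1 by 1.83. SPI1 is also a member of the general stress list. On chromosome X lie 4 members of the cell wall list. Of 37 oxidative stress genes 19 were higher, 5 lower and 13 not called (median 0.29, 19 and 5 adjusted over the list alone, camera adjusted p = 0.00202, adjusted p = 0.385 with an estimated correlation). The largest rises were those of OYE3 at 1.78, the glutathione transferase gene GTT1 at 1.36 and SOD1 at 1.33. Of 37 genes of the DNA damage response 17 were higher, 4 lower and 16 not called (median 0.19, 17 and 4 adjusted over the list alone, camera adjusted p = 0.0315, adjusted p = 0.385 with an estimated correlation). This call ended without chromosome X genes, where 4 of its members lie (adjusted p = 0.0547, median 0.17 without these members), and with ribosomal protein and biogenesis genes left out of the background (adjusted p = 0.0617). Its leading genes were the polyubiquitin gene UBI4 at 1.79, which is also a heat shock gene, the DNA glycosylase gene MAG1 at 1.18 and the ribonucleotide reductase gene RNR3 at 0.91.

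Genes of the translation machinery fell. The ribosome biogenesis list holds genes of assembly factors and RNA polymerase I subunits, and the regulator genes TOD6, DOT6 and STB3. Of its 161 genes 148 were lower, 1 was higher and 12 were not called, with a median log2 fold change of -0.56 (149 lower and 2 higher when adjusted over the list alone, camera adjusted p = 7.36e-35, adjusted p = 0.310 with an estimated correlation). The RNA helicase gene DBP2 fell from 718 ± 61.3 to 304 ± 21.2 CPM (SD, n = 2 each; log2 fold change -1.24), the nucleolin-like gene NSR1 fell by 1.01 and the assembly GTPase gene NOG2 by 0.90. The regulator gene TOD6, which is not an assembly factor gene, also fell by 0.90. NSR1 and NOG2 each overlap another feature. Of 137 cytosolic ribosomal protein genes 121 were lower, 6 higher and 10 not called (median -0.45, 122 and 6 adjusted over the list alone, camera adjusted p = 3.61e-21, adjusted p = 0.385 with an estimated correlation). These genes took 19.4% and 20.2% of the counts in the wild-type libraries and 15.8% and 17.0% in the mutant libraries. The largest falls were those of RPS22B at -1.49, RPL7B at -0.96 and RPL8A at -0.92, each a member of a pair of near-identical copies whose shared fragments were not counted. RPS22B also overlaps 1 other feature and RPL7B overlaps 2. The 6 ribosomal protein genes that were higher all lie on chromosome X, where 8 members of the list are found. Of 39 translation factor genes 33 were lower, 2 higher and 4 not called (median -0.36, 34 and 3 adjusted over the list alone, camera adjusted p = 1.46e-08, adjusted p = 0.385 with an estimated correlation). The initiation factor genes TIF3 and TIF4631 were each at -0.58 and the elongation factor gene YEF3 at -0.58. Of 21 genes of RNA polymerase III and its factors 11 were lower, 0 higher and 10 not called (median -0.22, 11 and 0 adjusted over the list alone, camera adjusted p = 0.0110, adjusted p = 0.385 with an estimated correlation). The largest falls were those of the subunit genes RPC31 at -0.75 and RPC53 at -0.59.

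Genes of respiration and of growth on other carbon sources were higher. Of 43 nuclear genes of oxidative phosphorylation 34 were higher, 0 lower and 9 not called (median 0.34, 34 and 0 adjusted over the list alone, camera adjusted p = 1.46e-08, adjusted p = 0.385 with an estimated correlation). The cytochrome c isoform gene CYC7 rose from 11.1 ± 1.61 to 48.5 ± 0.35 CPM (SD, n = 2 each; log2 fold change 2.13), the cytochrome oxidase isoform gene COX5B rose by 1.35 and CYC1, on chromosome X, by 0.97. CYC7 and COX5B are also members of the list of anaerobic and hypoxic genes, and CYC7 of the general stress list. Of 48 glucose-repressed genes 28 were higher, 5 lower and 15 not called (median 0.52, 28 and 5 adjusted over the list alone, camera adjusted p = 4.81e-05, adjusted p = 0.310 with an estimated correlation). The largest rises were those of SPG4 at 2.86, the hexokinase gene HXK1 at 2.26 and, on chromosome X, the transporter gene SFC1 at 2.12 and the activator gene SIP4 at 2.02. SPG4 rests on 7 and 10 counts in wild type and 60 and 96 in the mutant, and HXK1 overlaps another feature. The call of HXK1 ended without mutant replicate 1 (adjusted p = 0.190) and without mutant replicate 2 (0.293). In the retrograde response list 7 of 14 genes were higher, 1 lower and 6 not called (median 0.12, 7 and 1 adjusted over the list alone, camera adjusted p = 0.0318, adjusted p = 0.385 with an estimated correlation). The median was 0.19 without mutant replicate 1 and 0.082 without wild type replicate 1. The higher genes include those of the tricarboxylic acid cycle enzymes CIT1, IDH2 and IDH1, at 1.23, 1.21 and 0.82, and PYC1 of pyruvate carboxylase at 0.83. In the galactose regulon 5 of 9 genes were higher, 0 lower and 4 not called (median 0.30, 5 and 0 adjusted over the list alone, camera adjusted p = 0.0315, adjusted p = 0.385 with an estimated correlation). GAL7, at 1.24, rests on 16 and 42 counts in wild type, and was 0.82 without wild type replicate 1 and 1.95 without wild type replicate 2. The next largest rises were those of PGM2, the phosphoglucomutase gene, at 1.14 and the reductase gene GCY1 at 1.13, and PGM2 is also a member of the general stress list. The galactose call ended with library totals only (adjusted p = 0.0613), without mutant replicate 2 (0.0977), without wild type replicate 1 (0.0665) and without wild type replicate 2 (0.105).

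Several biosynthetic and uptake pathways were lower. Of 22 purine synthesis genes 16 were lower, 1 higher and 5 not called, with a median log2 fold change of -0.66 (16 and 1 adjusted over the list alone, camera adjusted p = 7.80e-07, adjusted p = 0.385 with an estimated correlation). ADE17, which acts in the last steps of the pathway and has a close paralog in ADE16, fell from 1389 ± 79.1 to 586 ± 72.6 CPM (SD, n = 2 each; log2 fold change -1.24), the purine permease gene FCY2 fell by 1.10 and the serine hydroxymethyltransferase gene SHM2 by 1.06. In the phosphate regulon 13 of 22 genes were lower, 3 higher and 6 not called (median -0.42, 13 and 4 adjusted over the list alone, camera adjusted p = 0.00135, adjusted p = 0.385 with an estimated correlation). PHO84, SPL2, VTC3 and PHM6 fell most. In the methionine and sulfate assimilation list 18 of 37 genes were lower, 4 higher and 15 not called (median -0.22, 18 and 4 adjusted over the list alone, camera adjusted p = 0.00196, adjusted p = 0.385 with an estimated correlation). MET14 fell by 1.02, the methionine synthase gene MET6 by 1.01 and the S-adenosylmethionine synthetase gene SAM2 by 0.97, whereas STR2, on chromosome X, rose by 1.07. Of 28 genes of ergosterol synthesis 15 were lower, 2 higher and 11 not called (median -0.20, 15 and 2 adjusted over the list alone, camera adjusted p = 0.00434, adjusted p = 0.385 with an estimated correlation). The squalene epoxidase gene ERG1 was at -0.87 and the lanosterol demethylase gene ERG11 at -0.78. The ergosterol call ended without wild type replicate 2 (median -0.12, adjusted p = 0.0505) and with fry (0.0501).

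Among cell cycle and chromatin genes, histone and daughter-cell genes were lower. Of 11 histone genes 9 were lower, 0 higher and 2 not called (median -0.44, 10 and 0 adjusted over the list alone, camera adjusted p = 8.58e-05, adjusted p = 0.385 with an estimated correlation). HTA1 was at -0.75 and HTB1 at -0.60, and these genes have close paralogs. In the list of M/G1 and daughter-cell genes 20 of 33 were lower, 4 higher and 9 not called (median -0.28, 21 and 4 adjusted over the list alone, camera adjusted p = 8.11e-05, adjusted p = 0.310 with an estimated correlation). The glucanase gene DSE4 fell by 0.93, SUN4 by 0.93, AMN1 by 0.91 and the mating-type endonuclease gene HO by 0.92. Nuclear pore and transport receptor genes were called slightly lower: 21 of 54 were lower, 5 higher and 28 not called (median -0.14, 21 and 5 adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.524 with an estimated correlation). The higher members were GSP2, a copy of the Ran gene, at 1.88, and, on chromosome X, NSP1 at 0.62, NUP192 at 0.58, NUP85 at 0.57 and NUP82, named after its value was seen. The nuclear pore call ended with library totals only (adjusted p = 0.131), where 8 genes were higher and 5 lower and the median was -0.0047, with fry (0.156), without mutant replicate 1 (0.0671), without mutant replicate 2 (0.195) and without wild type replicate 2 (0.339). The COS list was drawn by gene name. It holds genes of the COS multigene family and COS111, which shares the name but does not belong to that family. In this list 9 of 11 genes were higher, 0 lower and 2 not called (median 0.75, 9 and 0 adjusted over the list alone, camera adjusted p = 0.000397, adjusted p = 0.310 with an estimated correlation). COS111 was at 1.51 and COS1, of the family, at 1.02. Fragments shared between near-identical members of the family were not counted, so the values of the family are uncertain.

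**Figure D4:**
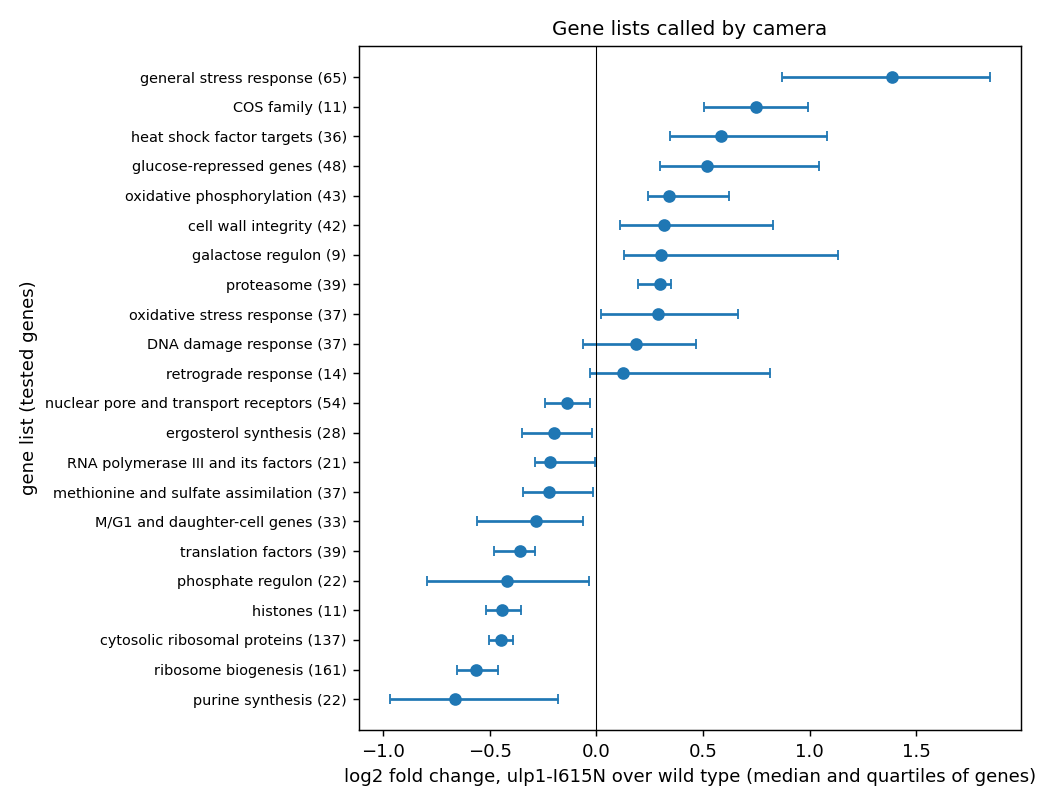
Median log2 fold change (ulp1-I615N over wild type) of the 22 gene lists called by camera with a preset correlation; points are medians and bars are the quartiles over the genes of each list, with the number of tested genes in brackets. The general stress response lies highest, at 1.38, and purine synthesis lowest, at -0.66.

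The SUMO pathway list, which holds SUMO, its enzymes and its targeted ubiquitin ligases, was not called by camera (adjusted p = 0.250). With fry this list was called lower (adjusted p = 0.0281). The median of the list was -0.10, with -0.06 without wild type replicate 2 and 0.03 with library totals only. Of its 14 genes 4 were lower, 1 higher and 9 not called (4 and 1 adjusted over the list alone), and with library totals only 1 was lower and 3 higher. The conjugating enzyme gene UBC9 fell from 79.1 ± 0.13 to 62.8 ± 2.67 CPM (SD, n = 2 each; log2 fold change -0.34 ± 0.07 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00121), and the ligase gene SIZ1 fell by 0.30, a call that ended with library totals only (-0.17, adjusted p = 0.133). The ligase gene MMS21 fell by 0.64, a call that ended with DESeq2 (adjusted p = 0.0661), with library totals only (0.0513), with thinning to the smallest total (0.0574), without mutant replicate 2 (0.140) and without wild type replicate 1 (0.0619). CST9 rose by 0.30, a call that ended with DESeq2 (adjusted p = 0.0781), without mutant replicate 2 (0.179) and without wild type replicate 2 (0.103). Lists that mark other cell types were not called either: of 4 alpha-cell genes 2 were higher and 0 lower (camera adjusted p = 0.138; 2 and 0 adjusted over the list alone), of which SAG1 lies on chromosome X and STE3 lost its call with each library left out in turn (adjusted p = 0.0662 to 0.108), with DESeq2 (0.121) and with thinning (0.0582). Of 39 genes of meiosis and sporulation 14 were higher and 5 lower (camera adjusted p = 0.129, with 14 and 5 adjusted over the list alone). With fry the alpha-cell list (adjusted p = 0.0137) and the meiosis list (adjusted p = 0.00792) were called higher. Among 215 tested genes within 20 kb of a chromosome end 67 were higher, 29 lower and 119 not called, and the set was not called by camera. Its median was 0.11 at this distance, 0.023 within 10 kb and 0.24 with library totals only.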

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

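Leaving out chromosome X and removing its median were chosen after seeing the data. The replicate block, a paired fit, gave 1778 higher and 1657 lower genes (3435 changed) against 1618 and 1489. The replicate numbers were not taken to pair the libraries, since the labels name no shared batch. Library names share a letter within each replicate number, but the labels do not say what it stands for. The differences of replicate 1 from replicate 2 correlated at 0.081 between the groups, over the tested genes. A shared batch is not excluded by this. With that block 21 lists were called, without the galactose regulon (adjusted p = 0.106) and the nuclear pore list (0.170) and with the zinc regulon (0.0108) added. Against a fold of 1.2, 1547 genes were changed (912 higher, 635 lower) instead of 3107, because that test asks for more than a difference from 0. With library totals only, 855 genes were lower instead of 1489, which follows the 0.13 shift of all genes, and the ULP1 log2 fold change of 0.26 passed (adjusted p = 0.0248). DESeq2 called 2575 genes, 2563 of them also called by edgeR and all of these in the same direction. With an estimated correlation 0 gene lists were called instead of 22. With fry 28 lists were called, without the nuclear pore and ergosterol lists and with the SUMO pathway, alpha-cell, meiosis, pheromone, Gcn4, glycolysis, unfolded protein response and zinc lists added. The count of shifted chromosomes was 1 in the main test, 7 with fry, which does not compare a set with other genes, and 0 without chromosome X genes or with its median removed, as both remove the shift by construction. Subtelomeric genes, not called at 20 kb, were called with fry (median 0.11) and with the chromosome X median removed (median 0.11); the cause was not tested. With that median removed, 7 named genes of chromosome X turned below 0: ASF1 (-0.029), JEM1 (-0.018), MRPL49 (-0.12), MRPL8 (-0.14), NSP1 (-0.11), NUP192 (-0.14) and NUP85 (-0.15), again by construction. With each library left out in turn, 2595 to 3030 genes were changed (1368 to 1528 higher, 1227 to 1502 lower), 349 to 405 of them at least 2-fold, 21 to 24 lists were called, 1 chromosome was shifted, the ULP1 value ran from 0.05 to 0.19 and the subtelomeric median from 0.13 to 0.18. Over all alternatives, single named genes stayed on their side of the threshold without a called change of direction in 2803 comparisons, lost the call in 67, gained it in 5 and reversed in the 7 above. List tests stayed on their side in 549, lost the call in 38 and gained it in 24. These counts of comparisons that stayed include values not called whose sign changed, such as the SUMO pathway median with library totals only (0.03). Depth limits how low an amount can be told from 0, which is 0.227 CPM in the shallowest library, and thinning to the smallest total gave 3021 changed genes.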

Other observations

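The tests of an extra whole chromosome, of a lower output per copy, of a raised chromosome X as the origin of the stress response, and both tests on PRM7 and BSC1 were chosen after the results were seen.

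Several lists moved in both directions and were not called by camera. In glycolysis and fermentation 8 of 23 genes were higher and 10 lower: TDH1 and the glucokinase gene GLK1 rose by 3.17 and 2.16 on the log2 scale, while the list's median was -0.15 and its mean 0.38, so that its median differs in sign from its mean and from the direction of the test (camera adjusted p = 0.880, and 0.0232, 0.0248 and 0.0170 without mutant replicate 2, wild type replicate 1 and wild type replicate 2). In the zinc regulon 8 of 16 genes were lower and 5 higher (adjusted p = 0.0842, and 0.00259 to 0.0117 with any 1 of the 4 libraries left out, and 0.0474 with library totals only), with ZRT1 at -1.70 and the low-affinity metal transporter gene FET4 at -1.10. Among iron regulon genes 7 of 29 were higher and 5 lower (adjusted p = 0.347), with the haem oxygenase gene HMX1 at 1.55 and FRE4 at -1.53. Among hexose transporters 8 of 15 were higher and 2 lower (adjusted p = 0.0842, and 0.0260 without wild type replicate 1), led by HXT9, on chromosome X, at 1.95, and these genes have close paralogs. Among anaerobic and hypoxic genes 4 of 20 were higher and 7 lower (adjusted p = 0.194), with the desaturase gene OLE1 at -1.07, and the median of -0.33 differs in sign from the mean of 0.0065. In the unfolded protein response 11 of 29 genes were higher and 5 lower (adjusted p = 0.218), and the leading members INO1, KAR2 and JEM1 all lie on chromosome X, with JEM1 at 0.71. The pheromone response had 12 of 33 genes higher and 6 lower (adjusted p = 0.139), with FIG1 at 2.08 and PRM5 at 1.42.

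The remaining lists gave these counts, with camera adjusted p. Gcn4-controlled amino acid synthesis had 13 higher and 26 lower of 63 genes (0.103, and 0.0182 without chromosome X genes and 0.0274 without ribosomal protein and biogenesis genes), with the glutamine synthetase gene GLN1 at -0.98. G1/S genes had 12 higher and 21 lower of 63 (0.194, and 0.0378 with the chromosome X median removed), and G2/M genes had 10 higher and 9 lower of 33 (0.905), with a median of 0.06 above 0 but a mean of -0.024 and a test direction below 0. Mitochondrial ribosomal proteins had 6 higher and 0 lower of 76 (0.502), pleiotropic drug resistance 8 and 3 of 20 (0.180), silencing and telomere factors 1 and 7 of 23 (0.180), seripauperins 3 and 0 of 12 (0.414), a-cell genes 2 and 1 of 7 (0.406), and flocculins and adhesins 1 and 1 of 8 (0.656). Adjusted over the list alone, these counts differed for mitochondrial ribosomal proteins (5 higher), seripauperins (2 higher), silencing factors (6 lower) and G2/M genes (11 higher). With library totals only the counts became 19 higher and 20 lower for Gcn4-controlled genes, 17 and 6 for G1/S genes and 3 and 3 for silencing factors, and the medians of these lists moved from -0.07, -0.09 and -0.045 to 0.06, 0.04 and 0.09. Mitochondrial ribosomal proteins then had 16 higher and a median of 0.15. In the main test 4 of their 6 higher genes lie on chromosome X, and 2 of the 72 genes elsewhere were higher. In lists with at least 3 tested members on chromosome X, these stood above the other members by their medians, except in the general stress response (1.35 on chromosome X, 1.39 elsewhere). The 18 tested genes of ribosomal proteins, ribosome assembly and translation factors on chromosome X had a median of 0.21, with 8 higher and 0 lower, and the 319 elsewhere had a median of -0.49. The difference of 0.70 compares with 0.74 between all genes of chromosome X and all genes elsewhere.

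The rise of chromosome X genes was weighed first. A bias by GC content or gene length was argued against, since the median of chromosome X stayed at 0.69 after a fit on both over the other chromosomes was removed, and so were listed stress and other genes that lie there, since the genes of chromosome X in no list had a median of 0.73. An extra copy of the whole chromosome in the mutant strain is a candidate explanation: the lowest window of 20 neighbouring genes in either mutant library was 0.44. The median of 0.73 lies below the 1 that a doubled output would give, so an extra copy may be present in part of the cells or may give a lower output per copy. The median does not tell these readings apart. The value of 1 also assumes a single copy in wild type, and ploidy was not measured here. No DNA was measured here, and whether the rise of chromosome X genes belongs to the ulp1-I615N strain or arose in the cultures stays open.

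For the rise of general stress genes with the fall of ribosome biogenesis genes, members on chromosome X are too few to carry the pattern. They are 3 of 65 stress genes and 7 of 161 ribosome biogenesis genes. The stress list without them had a median of 1.39 and kept its camera call with a preset correlation (adjusted p = 0.310 for the whole list with an estimated correlation). Leaving out so few genes could hardly have changed this. The ribosome biogenesis list without them had a median of -0.57. Mutant cultures nearer to glucose depletion at harvest could contribute, because the glucose-repressed list had a median of 0.52 and was called higher with a preset correlation (adjusted p = 0.310 with an estimated correlation), and this stays open. A response to the raised chromosome X and a response to the mutation in ULP1 cannot be told apart, as 0 mutant libraries lacked a raised chromosome X. Slower growth of the mutant, from either origin, was not tested.

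For PRM7 and BSC1, a deletion of both whole genes in all cells was argued against. The lowest count of either in a mutant library was 50, whereas the disrupted LYS1 had at most 5. LYS1 is a single benchmark, as ADE2 and ADE3, which the genotypes list as deleted, had at least 1368 counts in each library. A deletion in part of the cells is not excluded by these counts. A loss of like size that spans the neighbouring genes was argued against too, as the 5 tested genes on each side had a median of -0.19. Of these 10 genes 6 were called lower and 1 higher, against 1489 lower among all 6139 tested genes. The lowest of them, DBP10, was at -0.53. It belongs to the ribosome biogenesis list, whose median was -0.56, so its value does not point to a local fall. The next lowest, SIR2, was at -0.41, and a smaller fall around the pair is not excluded. A sequence difference between the strains within or before these genes may remain, and the lowest count of 50 does not exclude it; it was not tested here.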
